A study of Caenorhabditis elegans with 12 samples.

How the data were processed

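The series holds RNA sequencing of Caenorhabditis elegans larvae of the wild-type strain N2 at the first larval stage (L1), irradiated with ultraviolet B light (UVB) or mock treated. RNA was taken at 6 h after 800 mJ/cm2 or at 24 h after 480 mJ/cm2, so that dose and time differ together. Per the labels, RNA was extracted with TRIzol and bead homogenisation, cleaned on columns, and made into libraries by standard Illumina protocols. The 4 groups (UV at 6 h, mock at 6 h, UV at 24 h, mock at 24 h) hold 3 libraries each, 12 in all. Treatment and UV dose were taken from the treatment labels, and replicate numbers from the sample titles. No label says that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

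The deposited values are FPKM (fragments scaled to gene length and to the fragments sequenced), named so by the authors in their deposited tables, one table of 46245 WormBase gene IDs per time. The 2 tables were normalized separately, so every test of UV against mock stayed within a table. The submitters' processing notes name DESeq2, with no version and no role. The aligner, the counting program, the genome build and how reads shared by near-identical genes were treated are not given in the sources used here. Symbols were taken from a table of WormBase IDs and matched 43227 of the 46245 IDs. Biotypes and gene lengths came from the Ensembl annotation of WBcel235, which holds 45990 of the IDs. No coordinates are given, since the deposited tables name no build, and no GC content was computed, since no genome sequence was used here.

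FPKM carries no read total. The values of genes at up to 0.3 FPKM fall on steps, and the ratio of these steps to those of mock replicate 1 of the same table estimates what 1 read was worth in each library. The ratio is 1 for that reference. In the other libraries it lay between 0.756 (UV replicate 3) and 0.897 (UV replicate 2) at 6 h, so that a read was worth most in mock replicate 1, and between 1.003 (UV replicate 1) and 1.139 (mock replicate 3) at 24 h. The absolute depth is unknown, and no counting interval is given. Some exact zeros sit beside high values: 103 genes at 6 h and 201 at 24 h had a 0 in a library and at least 10 FPKM in another. Such a gene is described as listed at 0, with the value of each library and no fold.

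Genes with at least 1 FPKM in at least 3 of the 6 libraries of a time were tested, 13766 at 6 h and 14607 at 24 h. The values were put on the log2(FPKM + 0.5) scale, which understates the change of low genes, and fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend). A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Changes are log2 differences, UV minus mock, with the standard error (SE) of the limma fit, and levels are mean FPKM ± SD of 3 libraries. The 24 h change minus the 6 h change was tested with limma over 4 group means on the 13142 genes tested at both times. The overlap of calls was tested with Fisher's exact test, one-sided. Gene lists were tested with camera of limma at a preset correlation between genes of 0.01 and again with an estimated correlation, on 50 lists fixed before the data were examined, of which 48 had at least 5 tested members at 6 h and 47 at 24 h. The list test of the difference between times was added afterwards.

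Genes named in the text follow a rule fixed before the data were examined. For each time these are the 8 largest rises and the 8 largest falls among changed genes with a symbol and a mean of at least 5 FPKM in the higher group, members of called lists with the smallest adjusted p, 20 fixed genes, and the 5 largest differences between times each way. The rule takes up to 4 members of every called list. In the text 2 members are named of each of the 11 lists with the smallest camera p, a limit set after the data were examined. numr-1 stands for 2 gene IDs that share the symbol, so its reads could be split between copies and its values are uncertain. The same holds for other multigene families, such as fipr, col, clec and fbxa.

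On simulated data with known changes, drawn from the spread of these libraries, the 6 h step on 13766 genes recovered 67.2% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 97% of those changed 4-fold, with 8 false calls. The 24 h step on 14607 genes recovered 0% at 1.5-fold and at 2-fold and 47% at 4-fold, with 0 false calls. The step for the difference between times on 13142 genes recovered 11.3% at 1.5-fold, 42.4% at 2-fold and 75.6% at 4-fold, with 33 false calls. Beside the 14, 50 and 93 genes recovered, these false calls are more than the threshold on adjusted p is meant to let through. Calls of the difference between times may thus be too many, and its p-values too small. The recovered shares hold for sets with few changed genes (67, 67 and 66 per fold at each time). With more changed genes the threshold on p is less strict, which was not simulated. The spread was drawn for each gene and library independently. A library that deviates in many genes together, such as replicate 3 at 24 h, was thus not simulated, and the false calls do not cover it.

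The alternatives were other pseudocounts and filters, median centring, quantile normalization, no trend, a replicate block, each library left out in turn, a 2-fold minimum, and rank-based or estimated-correlation camera. Array weights, leaving out genes with zeros beside high values, rescaling to the protein-coding total, leaving out both replicate 3 libraries of 24 h, and a separate spread for each time were added after the data were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.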

Results

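Gene expression was measured by RNA sequencing in L1 larvae of C. elegans 6 h and 24 h after UVB or mock treatment, with 3 libraries per group. UVB forms DNA lesions that block transcription and replication. The libraries of a group at 6 h were close to each other (Pearson's r across genes 0.984 to 0.988 within a group and at most 0.810 between groups). At 24 h, replicates 1 and 2 of a group had an r of 0.956 (mock) and 0.959 (UV), whereas replicate 3 stood apart from them in both groups, with an r of 0.911 to 0.913 in mock and 0.856 to 0.865 in UV. UV replicates 1 and 2 had a higher r with a mock library of 24 h (up to 0.893 and 0.895) than with UV replicate 3, whose own r with mock reached 0.802. The tables also differed in kind. Protein-coding genes held 98.1% to 98.6% of the summed FPKM in each 6 h library and 12.64% to 16.04% in each 24 h library, where ribosomal RNA held 72.5% to 78.3% in mock and 64.02% to 73.6% in UV. Levels are therefore compared within a time and not between times.

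The first comparison asked which transcripts differed between irradiated and mock larvae at 6 h after 800 mJ/cm2. Genes that build the cuticle fell furthest. The collagen sqt-3 (WBGene00005018) fell from 3137 ± 88.95 to 15.8 ± 6.27 FPKM (n = 3 per group; log2 change -7.68 ± 0.29, limma adjusted p = 4.35e-07). The collagens sqt-1 (WBGene00005016), rol-6 (WBGene00004397) and lon-3 (WBGene00003057) fell with log2 changes of -7.54 ± 0.15, -7.32 ± 0.14 and -7.30 ± 0.22. The hedgehog-related genes wrt-2 (WBGene00006948) and wrt-1 (WBGene00006947) had log2 changes of -7.55 ± 0.26 and -7.51 ± 0.18, the ground-like gene grl-7 (WBGene00001716) -7.39 ± 0.13, and sups-1 (WBGene00017716) -7.34 ± 0.15. Of the 110 tested genes of moulting and the apical matrix, 87 fell and 16 rose (median log2 change -2.17, camera adjusted p = 1.82e-12, adjusted p = 0.164 with an estimated correlation). Among them wrt-4 (WBGene00006950) fell from 101 ± 3.93 to 0.565 ± 0.0965 FPKM and grd-5 (WBGene00001694) from 271 ± 6.41 to 8.09 ± 0.838 FPKM.

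Cuticle collagens as a whole went both ways at 6 h, with 67 of 107 lower and 36 higher (median log2 change -1.76, camera adjusted p = 0.00217, adjusted p = 0.416 with an estimated correlation). Whether irradiated and mock larvae were at the same point of the moulting cycle at 6 h was not tested. The collagen col-80 (WBGene00000656) rose from 0.924 ± 0.179 to 109 ± 3.78 FPKM (log2 change 6.28 ± 0.099), col-147 (WBGene00000720) from 9.57 ± 0.0499 to 708 ± 46.2 FPKM (6.14 ± 0.050) and col-160 (WBGene00000733) from 7.80 ± 1.99 to 568 ± 22.4 FPKM (6.13 ± 0.16). The collagen col-142 (WBGene00000715) was listed at 0, 0.378 and 0.139 FPKM in the mock libraries and at 34.5, 38.7 and 34.8 FPKM in the UV libraries. The largest rises were in fungus-induced protein related genes, which encode small secreted peptides. fipr-24 (WBGene00007992) rose from 1.63 ± 0.583 to 449.9 ± 14.7 FPKM (log2 change 7.76 ± 0.20, adjusted p = 7.32e-08) and fipr-22 (WBGene00007989) from 1.95 ± 0.318 to 198 ± 19.03 FPKM (log2 change 6.34 ± 0.11). fipr-26 (WBGene00009963) was listed at 0, 0.718 and 1.38 FPKM in the mock libraries and at 235.9, 175.5 and 155.1 FPKM in the UV libraries. dod-22 (WBGene00010125), a gene known to respond to infection and to the FOXO factor DAF-16, rose from 1.92 ± 0.805 to 175 ± 7.11 FPKM (log2 change 6.24 ± 0.25).

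Several groups linked to pathogens and detoxification rose at 6 h, while epidermal antimicrobial peptides (camera adjusted p = 0.0613), oxidative stress genes (0.0875) and cytochrome P450 genes (0.103, 29 higher and 12 lower of 52) were not called. The antimicrobial peptides were called higher without mock replicate 2 (0.0431) or 3 (0.0467), and oxidative stress genes with quantile normalization (0.0491). In the intracellular pathogen response list, 34 of 40 genes rose and 1 fell (median log2 change 1.97, camera adjusted p = 2.17e-07, adjusted p = 0.0761 with an estimated correlation). Here skr-3 (WBGene00004809) rose from 115 ± 2.03 to 274 ± 8.21 FPKM and pals-23 (WBGene00016218) from 12.22 ± 0.551 to 50.3 ± 1.95 FPKM. F-box and BTB domain genes, whose products serve as ubiquitin ligase adaptors, rose in 123 and fell in 9 of 179 (median log2 change 0.71, camera adjusted p = 4.20e-07, adjusted p = 0.164 with an estimated correlation). fbxa-37 (WBGene00013845) went from 7.63 ± 0.535 to 88.6 ± 5.37 FPKM and fbxa-79 (WBGene00022329) from 5.01 ± 0.567 to 47.4 ± 2.81 FPKM. C-type lectins rose in 62 and fell in 17 of 100, or 18 lower when adjusted over the list alone (median log2 change 0.63, camera adjusted p = 3.04e-04, adjusted p = 0.164 with an estimated correlation). clec-67 (WBGene00018971) rose from 8.71 ± 0.349 to 178 ± 1.54 FPKM and clec-265 (WBGene00019738) from 31.4 ± 0.709 to 342 ± 6.96 FPKM. Glutathione S-transferases, which conjugate reactive compounds, rose in 29 of 39 (30 when adjusted over the list alone) and fell in 5 (median log2 change 0.99, camera adjusted p = 4.00e-04, adjusted p = 0.164 with an estimated correlation). gst-20 (WBGene00001768) rose from 42.4 ± 0.580 to 341 ± 11.4 FPKM and gst-24 (WBGene00001772) from 17.2 ± 2.68 to 318 ± 10.1 FPKM. Nuclear hormone receptors rose in 126 of 196 (127 when adjusted over the list alone) and fell in 30 (median log2 change 0.44, camera adjusted p = 2.92e-04, adjusted p = 0.164 with an estimated correlation). nhr-112 (WBGene00003702) went from 1.38 ± 0.123 to 20.6 ± 0.959 FPKM and nhr-7 (WBGene00003606) from 10.5 ± 0.760 to 55.9 ± 1.84 FPKM. Lysozymes, caenopores and other immune effectors rose in 38 and fell in 12 of 56 (median log2 change 0.57, camera adjusted p = 0.00324, adjusted p = 0.281 with an estimated correlation). UDP-glucuronosyltransferases rose in 37 and fell in 11 of 56 (median log2 change 0.63, camera adjusted p = 0.0104, adjusted p = 0.339 with an estimated correlation).

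Genes induced by FOXO (DAF-16), the transcription factor under insulin signalling, rose in 24 and fell in 2 of 29 at 6 h (median log2 change 0.67, camera adjusted p = 4.00e-04, adjusted p = 0.171 with an estimated correlation). FOXO-repressed genes did not go the opposite way, with 12 higher and 6 lower of 18 (median log2 change 0.57), and were not called (camera adjusted p = 0.142). The long noncoding RNA tts-1 (WBGene00006650) rose from 331 ± 35.4 to 1570 ± 33.7 FPKM, the linker histone gene hil-1 (WBGene00001852) from 2.41 ± 0.465 to 34.9 ± 1.90 FPKM, and the superoxide dismutase gene sod-3 (WBGene00004932) from 2.90 ± 0.309 to 12.8 ± 1.47 FPKM. daf-16 (WBGene00000912) itself rose from 59.6 ± 4.60 to 93.2 ± 4.103 FPKM. Nucleotide excision repair genes rose in 17 and fell in 3 of 22 (median log2 change 0.32, camera adjusted p = 0.0420, adjusted p = 0.298 with an estimated correlation), a call that ended without mock replicate 1 (camera adjusted p = 0.0508). The transcription-coupled repair gene csb-1 (WBGene00000803) rose from 2.30 ± 0.0988 to 6.74 ± 0.864 FPKM (log2 change 1.36 ± 0.11, adjusted p = 3.10e-05) and xpa-1 (WBGene00006963) from 21.5 ± 1.82 to 30.2 ± 0.949 FPKM. The global-genome repair gene xpc-1 (WBGene00022296) was at a log2 change of 0.15 ± 0.087 (adjusted p = 0.165) and the translesion polymerase gene polh-1 (WBGene00018721) at -0.22 ± 0.087 (adjusted p = 0.0583), neither called, though polh-1 was called lower with median centring (adjusted p = 0.0371). The p53 homologue cep-1 (WBGene00000467) was not called (log2 change 0.24 ± 0.13, adjusted p = 0.128), but was called higher without mock replicate 1 (0.36, adjusted p = 0.0191). egl-1 (WBGene00001170), which starts apoptosis, rose from 1.54 ± 0.566 to 3.996 ± 0.818 FPKM. The list of p53 and apoptosis genes was not called (14 higher and 9 lower of 29, camera adjusted p = 0.815), nor was that of other DNA repair and checkpoint genes (24 higher and 6 lower of 49, camera adjusted p = 0.118).

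Ribosomal protein genes rose by a little at 6 h, 77 higher and 1 lower of 81 (median log2 change 0.23, camera adjusted p = 3.28e-09, adjusted p = 0.281 with an estimated correlation), and this call ended with quantile normalization (adjusted p = 0.812). rpl-24.2 (WBGene00004437) rose from 184 ± 5.80 to 429 ± 16.997 FPKM, rpl-35 (WBGene00004449) from 3575 ± 107 to 4958 ± 70.8 FPKM and rps-1 (WBGene00004470) from 5539 ± 86.4 to 6544 ± 118 FPKM. The call of rps-1 ended with quantile normalization (log2 change 0.019). Ribosome biogenesis genes rose in 23 and fell in 4 of 42 (median log2 change 0.28, camera adjusted p = 0.0217, adjusted p = 0.528 with an estimated correlation), while the nucleolar gene fib-1 (WBGene00001423) was not called (log2 change -0.12 ± 0.055), except as lower with median centring (adjusted p = 0.0317). Proteasome genes fell in 28 and rose in 1 of 33 (median log2 change -0.19, camera adjusted p = 2.20e-05, adjusted p = 0.171 with an estimated correlation). rpt-2 (WBGene00004502) went from 252 ± 2.02 to 198 ± 2.81 FPKM and rpt-1 (WBGene00004501) from 207 ± 3.41 to 162 ± 1.11 FPKM. Oxidative phosphorylation genes fell in 33 and rose in 3 of 46 (median log2 change -0.16, camera adjusted p = 1.03e-04, adjusted p = 0.195 with an estimated correlation). gas-1 (WBGene00001520) went from 209 ± 1.39 to 165 ± 1.86 FPKM and nuo-5 (WBGene00021562) from 117 ± 1.94 to 90.7 ± 0.627 FPKM. Mitochondrial ribosome genes fell in 43 and rose in 7 of 69 (median log2 change -0.18, camera adjusted p = 4.85e-04, adjusted p = 0.444 with an estimated correlation). Cell cycle and replication genes fell in 44 of 70 (45 when adjusted over the list alone) and rose in 14 (median log2 change -0.25, camera adjusted p = 0.00247, adjusted p = 0.164 with an estimated correlation).

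Neuron markers fell in 35 and rose in 2 of 44 at 6 h (median log2 change -0.81, camera adjusted p = 2.17e-07, adjusted p = 0.0761 with an estimated correlation). ida-1 (WBGene00002048) fell from 106 ± 3.595 to 42.3 ± 1.17 FPKM and the tubulin gene mec-12 (WBGene00003175) from 99.6 ± 2.93 to 35.6 ± 2.105 FPKM. Neuropeptides fell in 29 of 54 (30 when adjusted over the list alone) and rose in 15 (median log2 change -0.19, camera adjusted p = 0.0420, adjusted p = 0.281 with an estimated correlation). Autophagy and lysosome genes rose in 36 and fell in 5 of 56 (median log2 change 0.18, camera adjusted p = 0.00431, adjusted p = 0.273 with an estimated correlation). Fatty acid and lipid genes fell in 45 and rose in 28 of 84, or 29 higher when adjusted over the list alone (median log2 change -0.22, camera adjusted p = 0.0436, adjusted p = 0.402 with an estimated correlation). This call ended without UV replicate 3 (camera adjusted p = 0.0526). Markers of intestine, epidermis, pharynx and body wall muscle were not called (camera adjusted p = 0.0613, 0.346, 0.770 and 0.118), nor were lists that would mark adults or embryos (sperm 0.862, oocyte and eggshell 0.367, embryonic regulators 0.879). Intestine markers were called higher without mock replicate 3 (0.0482) or UV replicate 2 (0.0388). Insulin-like peptides (0.0613) were called lower without mock replicate 2 (0.0400) or UV replicate 2 (0.0388). The larval timing genes lin-14 (WBGene00003003) and lin-28 (WBGene00003014) rose from 25.5 ± 1.08 to 68.8 ± 3.92 FPKM and from 70.8 ± 2.096 to 123 ± 5.45 FPKM. The histone methyltransferase gene set-2 (WBGene00004782) rose from 13.04 ± 0.431 to 24.5 ± 1.07 FPKM, while the demethylase gene spr-5 (WBGene00005010) was not called (log2 change -0.029 ± 0.052). The stress genes gst-4 (WBGene00001752) and hsp-6 (WBGene00002010) rose from 68.1 ± 6.66 to 123 ± 5.40 FPKM and from 183 ± 7.25 to 213 ± 3.597 FPKM, and hsp-16.2 (WBGene00002016) fell from 4.89 ± 1.07 to 1.98 ± 0.766 FPKM. The chaperone gene hsp-4 (WBGene00002008) rose from 89.5 ± 2.56 to 96.7 ± 1.62 FPKM, a call that ended with median centring (adjusted p = 0.0578) and without mock replicate 1 (0.0577) or UV replicate 2 (0.0708). The muscle myosin unc-54 (WBGene00006789) fell from 302 ± 11.9 to 261 ± 4.93 FPKM. The adult collagen col-19 (WBGene00000608) stayed at or under 0.166 FPKM in all 6 libraries.

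In all, 10106 of 13766 genes (73.4%) changed at 6 h, 5485 higher and 4621 lower, and 3492 of them by at least 2-fold. After rescaling to the protein-coding total the majority turned, with 4678 higher and 5155 lower (47.6% higher, against 54.3% as deposited). The camera test called 21 of 48 lists, 12 higher and 9 lower. None of the 21 was called with an estimated correlation, where their adjusted p lay between 0.0761 and 0.528. Counts adjusted over the list alone were the same in 15 of the 21 lists and differed by 1 gene in the other 6.

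The second comparison asked the same of larvae 24 h after 480 mJ/cm2. The largest single rises included genes known from infection and xenobiotic responses. As lists, immune effectors (camera adjusted p = 0.418), C-type lectins (0.706, 25 higher and 16 lower of 94) and the intracellular pathogen response (0.973, 3 higher and 3 lower of 28) were not called. The infection response genes irg-5 (WBGene00009429) and irg-4 (WBGene00008584) rose from 6.03 ± 4.82 to 576 ± 145 FPKM (n = 3 per group; log2 change 6.98 ± 0.88, limma adjusted p = 0.0110) and from 12.4 ± 9.94 to 518 ± 114 FPKM (log2 change 5.97 ± 0.9987). sysm-1 (WBGene00011979) rose from 1.75 ± 1.25 to 239 ± 75.5 FPKM (log2 change 6.90 ± 0.57), dod-24 (WBGene00007875) from 9.16 ± 6.51 to 328 ± 64.9 FPKM and drd-50 (WBGene00018643) from 0.0687 ± 0.0209 to 31.7 ± 6.96 FPKM. Mock replicate 3 was far below mock replicates 1 and 2 for irg-5 (9.64, 7.89 and 0.560 FPKM in replicates 1, 2 and 3) and irg-4 (19.5, 16.8 and 1.05 FPKM). The same held for sysm-1 (2.57, 2.37 and 0.320 FPKM) and dod-24 (13.1, 12.7 and 1.65 FPKM), which enlarges these changes. The ABC transporter gene pgp-8 (WBGene00004002) rose from 0.445 ± 0.0724 to 55.6 ± 38.4 FPKM, and the metal-responsive gene numr-1 (WBGene00017270), uncertain because of its copy, from 0.0598 ± 0.0224 to 51.3 ± 54.8 FPKM. Replicate 3 held the highest UV value of both, with 34.8, 32.1 and 100.0 FPKM for pgp-8 and 20.4, 18.9 and 114.6 FPKM for numr-1 in UV replicates 1, 2 and 3. The pharyngeal myosin myo-1 (WBGene00002348) was listed at 0 in all 3 mock libraries and at 199.7, 200.4 and 224.2 FPKM in the UV libraries, while its 6 h values were all above 0 (48.4 to 50.2 FPKM in mock). Whether such zeros are failed estimates is not known, so it is not given as a rise. Genes that fell furthest included the lysosomal lipase lipl-3 (WBGene00020016), from 55.0 ± 19.6 to 1.17 ± 0.321 FPKM (log2 change -5.02 ± 0.29, adjusted p = 0.00301), the lectins clec-227 (WBGene00008593) and clec-60 (WBGene00014046), from 17.5 ± 6.27 to 1.32 ± 0.786 FPKM and from 67.2 ± 29.1 to 6.20 ± 2.73 FPKM, and scl-14 (WBGene00008625), from 23.1 ± 4.60 to 1.90 ± 0.107 FPKM. fipr-10 (WBGene00008245) fell from 55.4 ± 18.4 to 7.21 ± 6.54 FPKM (UV replicates 1, 2 and 3 at 6.08, 14.2 and 1.31 FPKM), the saposin-like spp-2 (WBGene00004987) from 479.9 ± 6.85 to 59.7 ± 25.33 FPKM and the lipid-binding far-2 (WBGene00001386) from 701 ± 473 to 67.2 ± 29.3 FPKM. The call of far-2 ended with quantile normalization (adjusted p = 0.0533), and its mock replicates 1, 2 and 3 were at 984, 965 and 155 FPKM. sqst-3 (WBGene00012067) was at 5.09, 5.93 and 4.81 FPKM in mock and at 0.216 and 0.166 FPKM in UV replicates 1 and 2, and was listed at 0 in UV replicate 3.

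Lists of protein synthesis genes were called higher at 24 h with a preset correlation, though not every member was called. Translation factors rose in 34 and fell in 1 of 48, or 41 and 1 when adjusted over the list alone (median log2 change 1.02, camera adjusted p = 2.17e-13, adjusted p = 0.394 with an estimated correlation). The release factor erfa-1 (WBGene00020269) rose from 29.3 ± 2.52 to 96.05 ± 1.5004 FPKM and the helicase inf-1 (WBGene00002083) from 35.02 ± 5.77 to 133 ± 11.9 FPKM. Ribosomal protein genes rose in 44 of 81, or 68 when adjusted over the list alone, and fell in 0 (median log2 change 0.46, camera adjusted p = 6.62e-13, adjusted p = 0.540 with an estimated correlation), and with quantile normalization the list was no longer called (median log2 change 0.051, adjusted p = 0.119). rpl-11.2 (WBGene00004423) rose from 2147 ± 93.4 to 3337 ± 145 FPKM, rla-1 (WBGene00004409) from 3100 ± 312 to 4876 ± 32.7 FPKM and rpl-35 (WBGene00004449) from 3018 ± 34.5 to 5087 ± 1110 FPKM, and these 3 calls ended with median centring (adjusted p = 0.0844, 0.0743 and 0.109 for rla-1, rpl-11.2 and rpl-35) and with quantile normalization (0.2998, 0.192 and 0.159). rps-1 (WBGene00004470) was at a log2 change of 0.39 ± 0.11 (adjusted p = 0.0602), called higher without UV replicate 3 (0.0358) or both replicate 3 libraries (0.00868). Ribosome biogenesis genes rose in 31 of 42, or 34 higher and 1 lower when adjusted over the list alone (median log2 change 0.94, camera adjusted p = 1.89e-11, adjusted p = 0.219 with an estimated correlation). lpd-6 (WBGene00003062) went from 13.2 ± 2.02 to 53.4 ± 8.98 FPKM, nol-16 (WBGene00013958) from 20.8 ± 0.550 to 50.2 ± 3.11 FPKM and the fibrillarin gene fib-1 (WBGene00001423) from 78.4 ± 21.5 to 244 ± 44.1 FPKM. Aminoacyl-tRNA synthetases rose in 16 of 20, or 18 when adjusted over the list alone (median log2 change 1.08, camera adjusted p = 1.10e-07, adjusted p = 0.394 with an estimated correlation). pars-1 (WBGene00004189) rose from 50.3 ± 9.73 to 165 ± 30.2 FPKM and tars-1 (WBGene00006617) from 48.2 ± 5.02 to 127 ± 22.4 FPKM. Mitochondrial ribosome genes rose in 20 of 69, or 34 when adjusted over the list alone (median log2 change 0.49, camera adjusted p = 7.58e-08, adjusted p = 0.394 with an estimated correlation). mrpl-53 (WBGene00008459) went from 23.7 ± 1.60 to 58.04 ± 8.52 FPKM and mrpl-20 (WBGene00012992) from 15.7 ± 0.671 to 29.7 ± 1.54 FPKM.

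Lists of the proteasome and of stress responses were called higher as well, again with members that were not called. Proteasome genes rose in 28 of 33, or 32 higher and 1 lower when adjusted over the list alone (median log2 change 0.78, camera adjusted p = 5.12e-10, adjusted p = 0.527 with an estimated correlation). pas-4 (WBGene00003925) went from 36.3 ± 4.76 to 71.3 ± 3.21 FPKM, rpn-11 (WBGene00004467) from 56.6 ± 3.75 to 105 ± 9.90 FPKM and rpt-2 (WBGene00004502) from 53.5 ± 9.64 to 93.9 ± 1.01 FPKM. The call of rpt-2 ended with median centring (adjusted p = 0.0709) and quantile normalization (0.108). Endoplasmic reticulum stress genes rose in 9 of 26, or 14 when adjusted over the list alone (median log2 change 0.80, camera adjusted p = 1.25e-05, adjusted p = 0.394 with an estimated correlation). The chaperone hsp-4 (WBGene00002008) rose from 29.9 ± 8.64 to 118 ± 38.9 FPKM. Heat shock genes rose in 13 and fell in 1 of 22, or 15 and 1 when adjusted over the list alone (median log2 change 1.15, camera adjusted p = 0.00412, adjusted p = 0.570 with an estimated correlation). hsp-16.2 (WBGene00002016) went from 2.25 ± 2.53 to 12.4 ± 1.69 FPKM, with mock replicates 1, 2 and 3 at 0.474, 1.14 and 5.14 FPKM. Mitochondrial stress genes rose in 8 of 18, or 12 when adjusted over the list alone (median log2 change 0.70, camera adjusted p = 0.00203, adjusted p = 0.389 with an estimated correlation). hsp-6 (WBGene00002010) went from 103 ± 12.62 to 182 ± 37.8 FPKM. The call of hsp-6 ended with median centring (adjusted p = 0.0828) and quantile normalization (0.0512). gst-4 (WBGene00001752) was not called (log2 change 1.52 ± 0.63, adjusted p = 0.141), but was called higher without both replicate 3 libraries (1.15, adjusted p = 5.52e-04). Nucleotide excision repair genes rose in 7 of 22, or 11 when adjusted over the list alone (median log2 change 0.65, camera adjusted p = 0.00412, adjusted p = 0.540 with an estimated correlation). csb-1 (WBGene00000803) rose from 1.83 ± 0.518 to 12.4 ± 8.88 FPKM, with UV replicates 1, 2 and 3 at 7.60, 6.91 and 22.6 FPKM, and egl-1 (WBGene00001170) from 0.154 ± 0.0746 to 2.18 ± 0.832 FPKM. xpa-1 (WBGene00006963), xpc-1 (WBGene00022296), polh-1 (WBGene00018721) and cep-1 (WBGene00000467) were not called (log2 changes 1.02 ± 0.29, -0.11 ± 0.16, 0.29 ± 0.26 and -0.055 ± 0.26), apart from xpa-1, called higher without UV replicate 3 (0.72, adjusted p = 0.0316) or both replicate 3 libraries (0.0209). The p53 and apoptosis list was not called (camera adjusted p = 0.0866), nor that of other DNA repair and checkpoint genes (0.0669). The latter was called higher with quantile normalization (0.0491) and without mock replicate 1 (0.0286) or 2 (0.0234). Genes of H3K4 methylation rose in 9 of 23, or 10 higher and 1 lower when adjusted over the list alone (median log2 change 0.52, camera adjusted p = 7.93e-04, adjusted p = 0.570 with an estimated correlation). Both the methyltransferase set-2 (WBGene00004782) and the demethylase spr-5 (WBGene00005010) rose, from 9.52 ± 2.22 to 22.7 ± 8.90 FPKM and from 13.3 ± 0.458 to 19.3 ± 0.928 FPKM, and both calls ended with median centring (adjusted p = 0.0743 for set-2 and 0.129 for spr-5) and quantile normalization (0.0649 and 0.175).

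Lists of energy metabolism and several lists of tissue markers were called lower at 24 h. Oxidative phosphorylation genes fell in 28 and rose in 0 of 46, or 32 and 1 when adjusted over the list alone (median log2 change -0.59, camera adjusted p = 4.72e-12, adjusted p = 0.394 with an estimated correlation). atp-4 (WBGene00020275) went from 676 ± 13.5 to 389 ± 16.96 FPKM and ucr-2.3 (WBGene00020757) from 14.9 ± 2.96 to 5.61 ± 0.260 FPKM. Genes of glycolysis, gluconeogenesis and the glyoxylate cycle fell in 12 of 26, or 15 when adjusted over the list alone (median log2 change -0.60, camera adjusted p = 8.51e-09, adjusted p = 0.182 with an estimated correlation). The aldolase aldo-2 (WBGene00017166) fell from 1133 ± 57.0 to 467 ± 27.3 FPKM and the dehydrogenase gpd-3 (WBGene00001685) from 865 ± 28.1 to 388 ± 57.7 FPKM. FOXO-induced genes fell in 9 of 31, or 10 when adjusted over the list alone (median log2 change -0.83, camera adjusted p = 4.89e-07, adjusted p = 0.182 with an estimated correlation). ttr-44 (WBGene00008341) went from 339.8 ± 18.3 to 86.8 ± 15.3 FPKM and the transhydrogenase nnt-1 (WBGene00003778) from 97.3 ± 19.9 to 18.9 ± 4.19 FPKM. sod-3 (WBGene00004932) and daf-16 (WBGene00000912) were not called (log2 changes -1.23 ± 0.51 and -0.45 ± 0.18). sod-3 was called lower without mock replicate 3 (adjusted p = 0.0483) or both replicate 3 libraries (0.00217), and daf-16 with quantile normalization (0.0430) or without both (0.00962). Fatty acid and lipid genes fell in 18 and rose in 4 of 84, or 19 and 4 when adjusted over the list alone (median log2 change -0.41, camera adjusted p = 4.06e-04, adjusted p = 0.394 with an estimated correlation). Neuropeptides fell in 9 of 54 and in 9 when adjusted over the list alone (median log2 change -0.86, camera adjusted p = 2.27e-08, adjusted p = 0.570 with an estimated correlation). nlp-20 (WBGene00003758) went from 71.8 ± 8.01 to 12.9 ± 2.80 FPKM and nlp-1 (WBGene00003739) from 44.8 ± 12.06 to 15.1 ± 2.62 FPKM. Neuron markers fell in 3 of 44, or 1 when adjusted over the list alone (median log2 change -0.82, camera adjusted p = 2.32e-06, adjusted p = 0.570 with an estimated correlation). Their share of called genes is to be read against 1017 lower of 14607 in all. cat-2 (WBGene00000296) went from 3.82 ± 0.438 to 0.976 ± 0.259 FPKM and cho-1 (WBGene00000501) from 16.8 ± 8.07 to 5.45 ± 0.914 FPKM. Mock replicate 3 was the highest for cho-1 (12.4, 11.9 and 26.1 FPKM in mock replicates 1, 2 and 3), nlp-1 (39.0, 36.8 and 58.7) and nlp-20 (66.0, 68.5 and 80.9), which enlarges these falls. For cat-2 it was the lowest (3.86, 4.24 and 3.37 FPKM). Body wall muscle markers fell in 13 of 34, or 15 when adjusted over the list alone (median log2 change -0.84, camera adjusted p = 1.75e-05, adjusted p = 0.598 with an estimated correlation). unc-54 (WBGene00006789) fell from 1153 ± 10.1 to 360.5 ± 160.2 FPKM. Markers of intestine, epidermis and pharynx were not called (camera adjusted p = 0.634, 0.438 and 0.330), but epidermis markers were called higher without UV replicate 3 (median 0.41, adjusted p = 0.00769) or both replicate 3 libraries (0.59, adjusted p = 4.36e-04).

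Further lists were called at 24 h. Cell cycle genes rose in 8 of 69, or 1 when adjusted over the list alone (median log2 change 0.34, camera adjusted p = 2.94e-04, adjusted p = 0.570 with an estimated correlation). Insulin-like peptides fell in 4 and rose in 2 of 29, or 7 and 2 when adjusted over the list alone (median log2 change -0.60, camera adjusted p = 0.00501, adjusted p = 0.540 with an estimated correlation). Germline markers fell in 9 and rose in 2 of 42, or 11 and 3 when adjusted over the list alone (median log2 change -0.34, camera adjusted p = 0.0234, adjusted p = 0.689 with an estimated correlation), and oocyte and eggshell genes, a list that would mark adults, fell in 2 of 21, as when adjusted over the list alone (median log2 change -0.37, camera adjusted p = 0.0145, adjusted p = 0.389 with an estimated correlation). The sperm list, which would also mark adults, was not called (0.438), and embryonic regulators had 4 tested genes, too few for the list test. Epidermal antimicrobial peptides rose in 3 of 17, or 6 when adjusted over the list alone (median log2 change 0.94, camera adjusted p = 0.0271, adjusted p = 0.672 with an estimated correlation), and FOXO-repressed genes in 7 of 16, or 9 when adjusted over the list alone (median log2 change 1.03, camera adjusted p = 0.0330, adjusted p = 0.394 with an estimated correlation). Glutathione S-transferases rose in 11 and fell in 3 of 39, or 13 and 3 when adjusted over the list alone (median log2 change 0.42, camera adjusted p = 0.0340, adjusted p = 0.394 with an estimated correlation). Oxidative stress genes rose in 8 of 30, or 9 when adjusted over the list alone (median log2 change 0.47, camera adjusted p = 0.0395, adjusted p = 0.394 with an estimated correlation), and UDP-glucuronosyltransferases rose in 12 and fell in 1 of 58, or 14 and 1 when adjusted over the list alone (median log2 change 0.35, camera adjusted p = 0.0473, adjusted p = 0.540 with an estimated correlation). Several of these calls ended when a library was left out. The germline call ended without mock replicate 1 (camera adjusted p = 0.101), mock replicate 2 (0.0796) or UV replicate 2 (0.0535) and with quantile normalization (0.119), which also ended the oocyte call (0.0670). The antimicrobial peptide call ended without UV replicate 1 (0.0668) or 2 (0.0643), and that of FOXO-repressed genes without UV replicate 2 (0.0570). The glutathione S-transferase call ended without mock replicate 3 (0.0711) or UV replicate 2 (0.0535), and the oxidative stress call without mock replicate 3 (0.120) or UV replicate 3 (0.0599). The UDP-glucuronosyltransferase call ended without mock replicate 3 (0.280), UV replicate 1 (0.0539) or UV replicate 2 (0.0621). Without both replicate 3 libraries the calls of FOXO-repressed genes (0.124), oxidative stress genes (0.0591) and UDP-glucuronosyltransferases (0.116) ended. Other lists were called only in such runs. Cilia genes (camera adjusted p = 0.0989) were called higher with quantile normalization (0.00807) and without mock replicate 3 (8.24e-04), UV replicate 2 (0.0303) or both replicate 3 libraries (0.0355). Histones (adjusted p = 0.139) were called higher without UV replicate 3 (median 0.65, adjusted p = 0.00747) or both replicate 3 libraries (0.71, adjusted p = 0.0269).

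Moulting and collagen genes at 24 h depended on replicate 3 of the UV group. The collagen sqt-3 (WBGene00005018) was at 729.8, 755.7 and 26.6 FPKM in UV replicates 1, 2 and 3, against 373.4, 377.8 and 232.8 FPKM in mock. Collagens were called lower as a list, with 3 lower and 4 higher of 121, or 1 and 1 when adjusted over the list alone (median log2 change -0.71, camera adjusted p = 0.00313, adjusted p = 0.808 with an estimated correlation), but without UV replicate 3 their median turned to 0.29 and the call ended (adjusted p = 0.136), and without both replicate 3 libraries they were called higher (0.34, adjusted p = 0.0335). The moulting list was not called (2 higher and 1 lower of 107, camera adjusted p = 0.382), its median lying at 0.016 and its mean at -0.040. Without UV replicate 3 its median was 0.61 and the list was called higher (camera adjusted p = 8.59e-06). Without UV replicate 1 or 2 it was called lower (median -0.38 and -0.34, adjusted p = 0.0259 and 0.0165). The larval timing genes lin-14 (WBGene00003003) and lin-28 (WBGene00003014) were not called (log2 changes -0.20 ± 0.26 and 1.37 ± 0.43, adjusted p = 0.618 and 0.0720). lin-28 was called higher without both replicate 3 libraries (1.34, adjusted p = 6.72e-04), and lin-14 moved to 0.080 without mock replicate 3 and to 0.070 without both. The adult collagen col-19 (WBGene00000608) stayed at or under 0.507 FPKM in all 6 libraries.

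**Figure D1:**
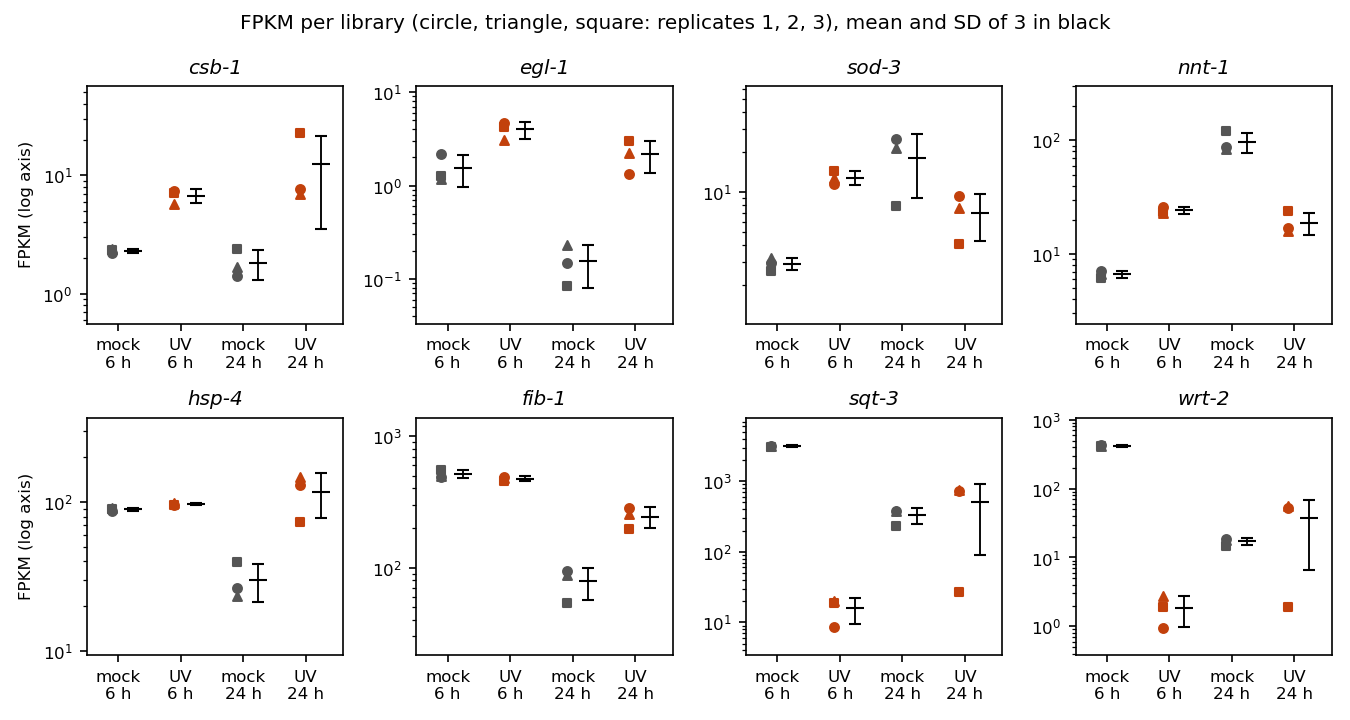
FPKM on a log axis in each library of the 4 groups (mock and UV at 6 h and 24 h, 3 libraries each) for 8 genes, with points for libraries, their shape for the replicate number, and the mean with its SD in black. The square of UV at 24 h, replicate 3, lies at 26.6 FPKM for sqt-3, far below the 729.8 and 755.7 FPKM of replicates 1 and 2.

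In all, 2823 of 14607 genes changed at 24 h, 1806 higher and 1017 lower, and 1631 of them by at least 2-fold. Higher genes made up 63.97% of the calls as deposited, but 43.3% after median centring, 46.8% after quantile normalization and 41.3% after rescaling to the protein-coding total. UV libraries lay above mock by 0.12 (log2) in the median of the tested genes and by 0.20 in the protein-coding total, so that a small rise at 24 h is to be read against that shift, which camera, comparing a list with the other genes, does not see. The count fell to 219, 75, 165 and 389 without mock replicate 1, mock replicate 2, UV replicate 1 and UV replicate 2, and rose to 4378 without UV replicate 3 and to 8429 without both replicate 3 libraries, which kept 2813 of the 2823 genes in the same direction. Of 58 called genes among those tracked by name, 20, 11, 20 and 27 stayed called without mock replicate 1, mock replicate 2, UV replicate 1 and UV replicate 2, and all 58 without both replicate 3 libraries. The camera test called 28 of 47 lists, 17 higher and 11 lower, and 0 of them with an estimated correlation (adjusted p from 0.182 to 0.808).

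**Figure D2:**
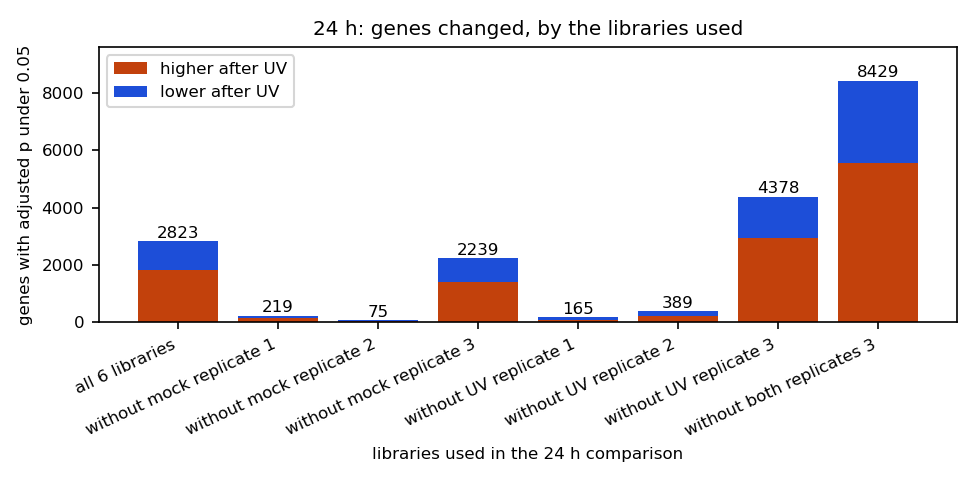
Number of genes with an adjusted p under 0.05 at 24 h (bars from 0, higher and lower genes stacked), by the libraries used. The count is 2823 with all 6 libraries, 75 to 4378 with 1 library left out, and 8429 without both replicate 3 libraries.

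The third comparison asked how the change at 24 h differed from that at 6 h, where dose and time cannot be told apart. FOXO-induced genes had the lowest adjusted p with an estimated correlation. They had a median log2 change of 0.67 at 6 h and -0.83 at 24 h, and 23 of 29 were lower at 24 h relative to 6 h (median difference -1.45, camera adjusted p = 2.57e-10, adjusted p = 0.0161 with an estimated correlation). nnt-1 (WBGene00003778) differed by -4.13 (limma adjusted p = 2.76e-06), tts-1 (WBGene00006650) by -3.77 and sod-3 (WBGene00004932) by -3.2001. Cytochrome P450 genes also differed with either correlation, 21 lower and 7 higher of 46 (median difference -0.70, camera adjusted p = 5.33e-04, adjusted p = 0.0466 with an estimated correlation), though the list was not called at 6 h (camera adjusted p = 0.103) or at 24 h (0.0531). At 24 h it was called lower without mock replicate 3 (0.00865), UV replicate 1 (0.0486) or both replicate 3 libraries (0.0364) and with a pseudocount of 0.1 (0.0496). Proteasome genes went from -0.19 to 0.78 in the median, and 31 of 33 were higher at 24 h relative to 6 h (camera adjusted p = 9.12e-11, adjusted p = 0.416 with an estimated correlation). Mitochondrial ribosome genes went from -0.18 to 0.49 (camera adjusted p = 1.43e-10, adjusted p = 0.257 with an estimated correlation), and glycolysis and related genes from 0.18 to -0.60 (camera adjusted p = 5.83e-08, adjusted p = 0.0706 with an estimated correlation). Genes of the intracellular pathogen response went from 1.93 to 0.21 (camera adjusted p = 2.62e-07, adjusted p = 0.257 with an estimated correlation).

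The largest single differences were in cuticle genes. The difference was 8.20 for lon-3 (WBGene00003057), 7.80 for wrt-1 (WBGene00006947), 7.70 for wrt-2 (WBGene00006948), 7.40 for sups-1 (WBGene00017716) and 7.30 for sqt-3 (WBGene00005018) (adjusted p from 0.00101 to 0.00332), all of them genes that fell at 6 h. It was -8.21 for col-160 (WBGene00000733), -8.18 for col-147 (WBGene00000720), -7.38 for col-80 (WBGene00000656), -6.79 for col-94 (WBGene00000669) and -6.42 for col-176 (WBGene00000749) (adjusted p from 1.40e-04 to 0.00115), collagens that rose at 6 h. At 24 h these genes varied between replicate 3 and the others, with SDs of 413.7 FPKM for sqt-3 and 277.4 FPKM for col-147 in the UV group.

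Of 13142 genes tested at both times, 5146 differed between times, 2909 higher and 2237 lower at 24 h relative to 6 h. Higher genes made up 56.5% of these as deposited, but 48.9% after median centring or quantile normalization and 48.7% after rescaling to the protein-coding total. Without both replicate 3 libraries of 24 h the count was 8911. The simulated test of the difference gave more false calls than its threshold is meant to let through, so these counts may be too high. At both times, 1043 genes were higher, where independent calls would give 705.9 (odds ratio 2.47, one-sided Fisher's exact test adjusted p = 9.45e-68), and 404 were lower, where they would give 301.5 (odds ratio 1.68, adjusted p = 2.60e-13). The number of genes changed the same way, 1447, fell to 128, 41, 93 and 237 without mock replicate 1, mock replicate 2, UV replicate 1 and UV replicate 2 of 24 h, and was 3453 without both replicate 3 libraries. Genes are not independent of each other, which these tests take them to be. Across genes, the changes at the 2 times had a Pearson's r of 0.269 and a Spearman's rho of 0.252, and 57.7% had the same sign.

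**Figure D3:**
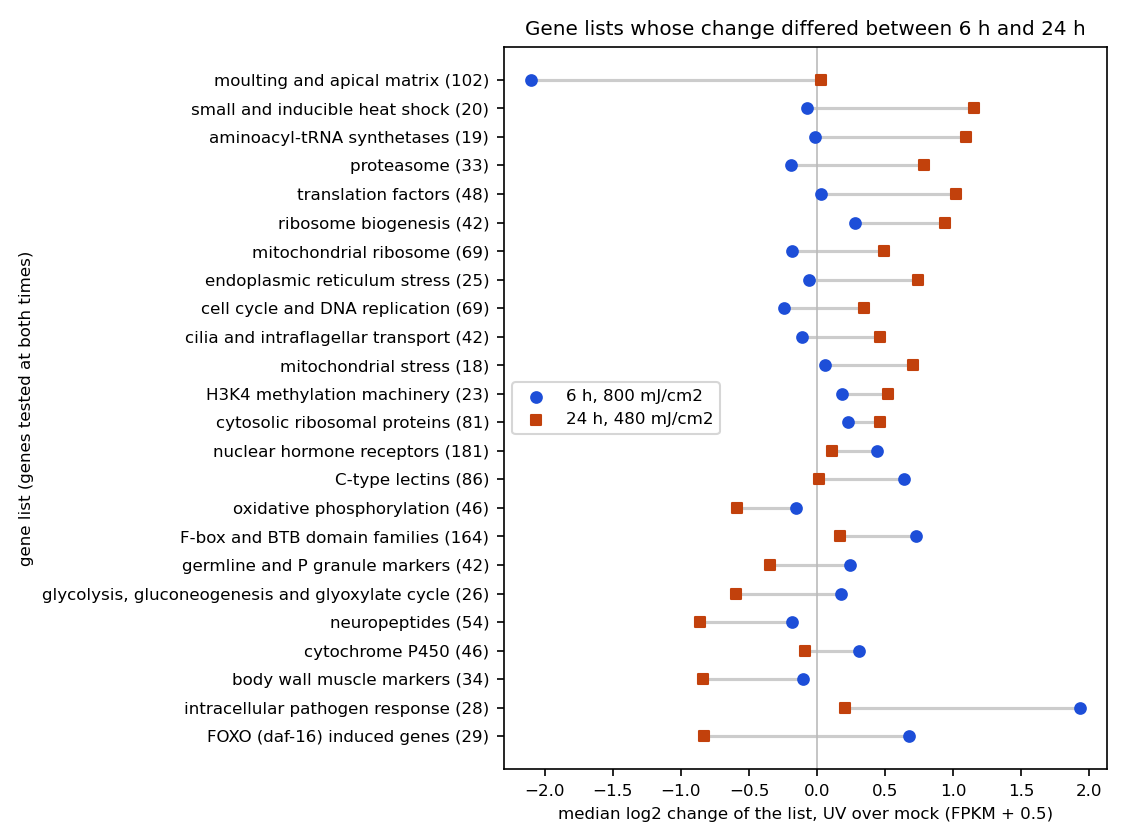
Median log2 change (UV over mock, on the log2(FPKM + 0.5) scale) of the 24 gene lists whose change differed between times by camera with a preset correlation, at 6 h (circles) and 24 h (squares), over the genes tested at both times (number in brackets). FOXO-induced genes moved from 0.67 to -0.83 and the moulting list from -2.099 to 0.030, and 2 of the 24 lists were called with an estimated correlation.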

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

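The list test of the difference between times, the tissue marker test of the translation lists and the tests of the FOXO and translation patterns with quantile normalization or without replicate 3 were chosen after the result was seen. The results here are those whose change at 24 h differed from that at 6 h by a test of the difference itself (camera with a preset correlation for lists), given as the 24 h minus the 6 h log2 change.

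Among lists, the median difference was above 0 for moulting and apical matrix (2.06), small and inducible heat shock (1.07), aminoacyl-tRNA synthetases (0.997), proteasome (0.96), translation factors (0.86), ribosome biogenesis (0.71), mitochondrial ribosome (0.70), endoplasmic reticulum stress (0.70), cell cycle and DNA replication (0.60), cilia and intraflagellar transport (0.57), mitochondrial stress (0.54), H3K4 methylation machinery (0.48) and cytosolic ribosomal proteins (0.24). It was below 0 for FOXO-induced genes (-1.45), intracellular pathogen response (-1.37), body wall muscle markers (-0.76), cytochrome P450 (-0.70), neuropeptides (-0.68), glycolysis, gluconeogenesis and glyoxylate cycle (-0.68), germline and P granule markers (-0.61), F-box and BTB domain families (-0.57), oxidative phosphorylation (-0.45), C-type lectins (-0.41) and nuclear hormone receptors (-0.33). With an estimated correlation only FOXO-induced genes (adjusted p = 0.0161) and cytochrome P450 genes (0.0466) of these 24 lists were called, and the others lay between 0.0706 (glycolysis and related genes) and 0.776 (cilia).

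Among cuticle and moulting genes the difference was above 0 for lon-3 (8.20), wrt-1 (7.80), wrt-2 (7.70), sups-1 (7.40), sqt-3 (7.30), sqt-1 (7.28), grl-7 (7.04), rol-6 (6.77), wrt-4 (5.099) and grd-5 (3.96). It was below 0 for the collagens col-160 (-8.21), col-147 (-8.18), col-80 (-7.38), col-94 (-6.79) and col-176 (-6.42). Among genes of protein synthesis and turnover it was inf-1 (2.05), pars-1 (1.98), erfa-1 (1.87), fib-1 (1.77), tars-1 (1.40), pas-4 (1.28), rpt-2 (1.17), rpn-11 (1.08), mrpl-20 (1.05), mrpl-53 (0.998), rpt-1 (0.93), nol-16 (0.88), lpd-6 (0.63), rla-1 (0.43), rpl-11.2 (0.41) and rpl-24.2 (-1.07). Among stress and immune genes it was hsp-16.2 (3.78), dod-24 (3.03), sysm-1 (2.21), hsp-4 (1.82), drd-50 (0.94), hsp-6 (0.58), pals-23 (-1.09), gst-20 (-1.43), clec-227 (-2.205), scl-14 (-2.90), spp-2 (-3.08), clec-60 (-4.12) and fipr-24 (-5.48). For FOXO and its targets it was daf-16 (-1.09), ttr-44 (-1.95), sod-3 (-3.2001), tts-1 (-3.77), nnt-1 (-4.13) and hil-1 (-5.67). For metabolism it was atp-4 (-0.69), ucr-2.3 (-0.92), gpd-3 (-1.57), aldo-2 (-1.91), far-2 (-2.73) and lipl-3 (-5.46). For the other named genes it was spr-5 (0.55), nlp-1 (-0.75), unc-54 (-1.59), lin-14 (-1.62) and nlp-20 (-1.96). Named genes listed at 0 in a library were left out of this account.

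FOXO-induced genes were higher at 6 h and lower at 24 h. The bootstrap limits here and in the next paragraph come from resampling the genes of a list, not the libraries. They take genes as independent and leave out the spread between libraries, so they may be too narrow. After median centring the median difference of the list was -1.54 (bootstrap 95% limits -2.31 to -1.16). This follows from the shift that centring takes from every gene alike (0.026 at 6 h and 0.12 at 24 h) and is no separate test. After quantile normalization the median difference was -1.51 (-2.40 to -1.14), no smaller in size than the -1.45 as deposited, which argues against the scaling of the libraries. Intestine markers without these genes differed by -0.24 (-0.55 to 0.28), and without both replicate 3 libraries by -0.054 (-0.73 to 0.28, against -1.49 for the list). As far as limits over genes can show, this argues against a smaller share of intestine RNA at 24 h. FOXO-repressed genes showed no such turn. Their median log2 change was 0.57 at 6 h and 1.03 at 24 h. The difference was higher in 3 and lower in 0 of 16 (median 0.24) and was not called (camera adjusted p = 0.597). For the FOXO-induced genes, candidate explanations are that UV acts on them in opposite ways at the 2 times or doses, or that the mock larvae changed with time. For tts-1, mock libraries held 293 to 363 FPKM at 6 h and 4670 to 8252 at 24 h. Its UV libraries held 1532 to 1597 and 1303 to 4089 FPKM. Mock libraries of nnt-1, hil-1 and sod-3 were also higher at 24 h, while UV libraries of sod-3 were lower. For ttr-44, mock libraries held 209 to 230 and 328 to 361 FPKM, and UV libraries 210 to 217 and 71 to 101. The tables were normalized separately, so these levels do not decide. The kind of library also stays open, as it was not tested.

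Translation-related genes (191 of ribosomal proteins, ribosome biogenesis, translation factors and tRNA synthetases) were higher at 24 h, with a median of 0.62 (0.56 to 0.71 over resampled genes). Members of these lists varied together (estimated correlation 0.67 for ribosomal proteins and 0.37 for translation factors), which such limits leave out. After a correction for exonic length the median was 0.67 (0.62 to 0.75), which argues against gene length. After median centring it was 0.50 (0.44 to 0.59), which follows from the shift of 0.12 taken from every gene and is no separate test. A factor of that size is not the whole cause. After quantile normalization it was 0.37 (0.20 to 0.51), with ribosomal proteins at 0.051 and no longer called (camera adjusted p = 0.119), so that a scaling which differs with expression level stays open. Of the tissue lists of intestine, epidermis, pharynx and germline, 4 of 4 had an upper limit below the lower limit of these genes, and 2 of 4 (pharynx and germline) without both replicate 3 libraries, where epidermis (0.59) reached them (0.50). As far as limits over genes can show, this argues against a lower share of muscle and neuron RNA as the whole cause. A response to UV may be a further explanation, which these tests do not decide, and dose and time differ together.

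Replicate 3 of both 24 h groups lay apart from replicates 1 and 2. Quantile normalization left the median deviation at 1.00 times its value in UV and 1.02 in mock, which argues against scaling. In the 10% of genes with the highest expression the deviation was 7.16 times that between replicates 1 and 2 in UV and 6.49 in mock, which argues against shallower sequencing. Moulting and collagen genes (227) deviated by a median of 2.62 in UV and 0.54 in mock, against 0.49 and 0.41 in random lists of like expression (percentile 100 and 99.97 of 10000). With the sign kept, they were lower by a median of 2.62 in UV, while the median was 0.015 in mock, with no common direction. Another point of the moulting cycle is thus a candidate explanation, mostly in UV. Replicate 3 had the lowest share of ribosomal RNA in both groups. It held 64.02% in UV, against 73.6% and 71.7% in replicates 1 and 2, and 72.5% in mock, against 78.3% and 77.1%. Its share of small nucleolar RNA was the highest in both groups. Deviations of mock replicate 3 correlated at 0.26 with those of UV replicate 3, and at -0.22 and -0.17 with UV replicates 1 and 2. A separate culture or preparation shared by both replicate 3 libraries is thus a further candidate explanation. No label beyond the replicate number sets these libraries apart, so it stays open, and no biological explanation from the design was tested.

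Other splits of the libraries were counted for each result. The 6 libraries of a time can be split in 10 ways, too few for a share under 0.05. At 6 h the real split called 10106 genes and the highest other 2 (1 of 10 splits as high), and 21 lists against 21 in the highest other (2 of 10). At 24 h it called 2823 genes against 5 (1 of 10) and 28 lists against 27 (1 of 10). For the difference between times, 2 of 100 splits drawn within each time gave as many as the real 5146 genes, the other of them being the real groups with UV and mock mirrored at 24 h (7094). For genes changed the same way, 1 of 100 splits gave as many as the real 1447 (highest other 640, again the mirrored one). A split that breaks the groups of a time shrinks the UV change and adds it to the spread, which settles its count of genes beforehand. This did not hold for lists, of which the mixed splits still called 14 to 21 at 6 h and 16 to 27 at 24 h. A mixed split sets unequal numbers of UV libraries against each other, so part of the UV change stays in it. These splits thus cannot show how many lists would be called without a UV effect. The number of lists called at the preset correlation is not taken as evidence of such an effect. Only 20 splits keep the 6 h groups (9 among those drawn), too few for a share under 0.05.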

How the results depend on the processing

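Array weights, the protein-coding total, a separate spread per time, leaving out genes with zeros and leaving out both replicate 3 libraries of 24 h were chosen after the data were seen. At 6 h the count of genes lay between 8329 and 10649 over other pseudocounts, filters and scalings, between 9493 and 9739 with a library left out, and at 3492 with a 2-fold minimum, the list count between 18 and 24 and between 20 and 23. At 24 h the count was 1841 without the filter on low values (more genes tested), 1631 with a 2-fold minimum, 9150 with array weights (0.149 and 0.0890 for mock and UV replicate 3), 8429 without both replicate 3 libraries, and between 75 (without mock replicate 2) and 4378 (without UV replicate 3) with a library left out. The 24 h list count was between 25 and 29 with a library left out. Camera with an estimated correlation called 0 lists at 6 h and 0 at 24 h, where 10390 and 5382 genes had an unadjusted p under 0.05, and rank-based camera 20 and 27. The difference between times gave 3036 genes with a 2-fold minimum, 8911 without both replicate 3 libraries, 6130 with a separate spread, and 4211 to 7025 with a library left out. Genes changed the same way numbered 899 without the filter, 535 with a 2-fold minimum, 3453 without both replicate 3 libraries, and 41 to 1844 with a library left out. Leaving out libraries leaves fewer samples, yet the 24 h count rose without UV replicate 3 and without both replicate 3 libraries. The cause of these moves was not tested. Directions with a call on either side turned for atp-4 at 6 h with quantile normalization (0.053), and at 24 h without UV replicate 3 or both replicate 3 libraries. With a library left out these lay, lowest to highest, at -1.28 to 0.29 for cuticle collagens, -0.38 to 0.61 for the moulting list, -1.78 to 0.48 for grd-5, -1.22 to 1.31 for grl-7, -1.07 to 1.33 for sqt-1 and -1.19 to 1.21 for sqt-3. Without both replicate 3 libraries they were 0.34, 0.60, 0.45, 1.21, 1.05 and 0.98, and rol-6 was 0.71. Values called in neither setting also changed sign, 22 times among 11 genes (wrt-1, -0.38, wrt-2, -0.57, and sups-1, -0.59, without UV replicate 1, for example) and 23 times among 8 lists. Of the 87 tracked genes called at 6 h, 86 stayed called with median centring and 82 with quantile normalization, and of 58 at 24 h 50 and 50. Same-numbered mock and UV libraries deviated together with correlations of -0.029, -0.095 and -0.035 at 6 h and 0.14, 0.10 and 0.26 at 24 h, not all high enough to pair them, and not every library correlated best with its own number. A replicate block gave 9806 genes at 6 h, 2698 at 24 h (2020 of them called the same way without it), 5816 differing between times, 1307 changed the same way, and 21 and 28 lists. At 24 h these 28 lacked FOXO-repressed genes (adjusted p = 0.0664) and held the cilia list (0.00862), which was also called in 4 other settings. Of the tracked genes at 24 h, the block ended the calls of cho-1 (0.0731), hsp-4 (0.0538), hsp-16.2 (0.0564), rpl-35 (0.0640) and spr-5 (0.0558) and called 10 others, among them sod-3 (-1.23, adjusted p = 0.0343), tts-1 (0.0362), lin-28 (0.0282) and gst-4 (0.0485). Absolute depth is unknown, so what depth limits for low genes cannot be stated.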

Other observations

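The families and biotypes here were chosen after the data were seen, by the prefix of the gene symbol, 96 at each time with at least 10 tested members. At 6 h the galectin genes (lec) rose in 12 of 12 (median log2 change 0.82, camera adjusted p = 0.000294), ABC transporters of the pgp family in 11 of 13 (1.63, adjusted p = 0.00517), chitinase-like chil genes in 13 of 15 (1.77, adjusted p = 0.00710) and nuclear pore genes (npp) in 20 of 25 (0.67, adjusted p = 0.00988). Genes of neuropeptide receptors (npr) fell in 28 of 39 (-0.64, adjusted p = 0.00206), ligand-gated channels (lgc) in 28 of 39 (-0.70, adjusted p = 0.00301) and touch receptor genes (mec) in 13 of 16 (-0.63, adjusted p = 0.00218). With an estimated correlation the adjusted p of these families lay between 0.398 and 0.436. Pseudogenes rose in 167 and fell in 23 of 297 at 6 h, with a median of 0.52, against 0.052 in protein-coding genes.

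At 24 h nuclear pore genes rose in 19 of 25 (median log2 change 0.94, camera adjusted p = 1.43e-08), RNA polymerase II subunits (rpb) in 9 of 11 (1.15, adjusted p = 3.11e-06), splicing genes (prp) in 10 of 13 (0.90, adjusted p = 2.39e-05) and secretory genes (sec) in 11 of 19 (0.67, adjusted p = 4.24e-06). Neuropeptide receptors fell in 13 of 40 (-0.83, adjusted p = 1.25e-09) and ligand-gated channels in 10 of 39 (-0.84, adjusted p = 1.99e-06). With an estimated correlation the adjusted p of all of these was 0.773. Small nucleolar RNAs rose in 11 and fell in 1 of 184, with a median of 0.33.

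One hypothesis was that lesions which block transcription lower long genes more than short ones at 6 h, with its test set before the result was seen. Across 13155 protein-coding genes, Spearman's rho of the log2 change on genomic span was -0.15, and -0.18 given exonic length, where genes are not independent replicates. The longest 10% of genes had a median change of -0.19 and 51.5% called lower, the shortest 10% 0.16 and 28.9%. Within 5 classes of expression rho lay between -0.24 and -0.056, and the weakest class missed the bound set for the hypothesis, so the data may fit it but do not decide. Without the neuron, muscle, cilia, moulting and collagen lists rho was -0.15. At 24 h it was -0.047 across 13122 genes, but -0.17 given exonic length, near the 6 h value, and the difference between times was not tested.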
